A study of Homo sapiens with 4 samples.

How the data were processed

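The 4 deposited libraries of HCT116 cells were used, 2 with a control shRNA (control_sh) and 2 with an shRNA against RBM25 (RBM25_sh), grouped by the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on columns and made into Illumina sequencing libraries. The submitters' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff 2.1.1 without their roles. The counting tool, its strand setting, the genome build and any filter are not given in the sources used here. Each library had 1 deposited table of whole-number counts per gene and 1 deposited table of FPKM per gene. The gene columns of both tables give an Ensembl gene ID, a name, a position, a length and a biotype for 58735 genes. The positions of all 58735 IDs equal those of GENCODE release 29 on GRCh38, and this build is used for coordinates. In 27 genes the name was held as a calendar date in the deposited tables and was taken from GENCODE by ID. Named genes that overlap another tested gene on either strand, among them SON, BCL2L2, SLC2A1, ANGPTL4 and FDFT1, are uncertain in so far as reads could be counted for either gene.

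The deposited FPKM equal the deposited counts divided by the listed gene length and by 1 factor per library, which corresponds to 1.06, 1.10, 0.951 and 0.998 times the library's total count. They therefore carry the same counts under another scaling, and were used only for alternatives. Library totals were 15528869 and 16982663 counts in the control libraries and 15528274 and 16335555 in the RBM25_sh libraries. Libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 71.2 between the controls and 26.8 between the RBM25_sh libraries, so none was treated as a duplicate.

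Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, libraries were scaled by TMM, and a quasi-likelihood F test compared RBM25_sh with control_sh with group as the only term, leaving 2 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment, and the threshold was an adjusted p of 0.05. The SE of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.252. With 2 libraries against 2, all interchangeable, 33.3% of genes would have groups that do not overlap by chance. In these data 51.8% did not overlap. Same-numbered libraries deviated together (correlation of 0.47 across genes), so the share to be met by chance here is not known.

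Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and 26 of 27 lists had at least 5 measured members. Benjamini-Hochberg adjustment ran over the 26 lists. The lists and the rule for named genes were fixed before the data were examined, as were the alternatives except the corrections for GC content and length. The rule takes RBM25 and MKNK2, and the 10 largest increases and the 10 largest decreases among called protein-coding genes with a symbol, an average log2 CPM of at least 3 and groups that do not overlap in CPM. It also takes up to 4 members of each list with the smallest adjusted p, of which a part is named; 1 list and 1 gene are not reported here. Markers of other cell types were among the lists.

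Alternatives were DESeq2 size factors in edgeR, library totals only, no filter, a stricter filter of 1 CPM in all libraries of a group, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, a replicate block, leaving out each library, a minimum change of 2-fold, and for lists an estimated correlation and the fry rotation test. Chosen after seeing the data were corrections that remove each library's smooth trend of log2 CPM on the GC content of the longest GENCODE transcript, with or without gene length, as offsets of the edgeR fit. A GC value was found for 99.95% of the genes tested. For lists, the estimated correlation rests on 2 residual degrees of freedom, and camera then also uses 2 for its test. Few lists could pass under it, so a call lost there does not show that correlated genes had made the call. Tests of transcript usage and of MKNK2 transcript shares had been planned for counts per transcript and were not run, since the counts are per gene. Figures were drawn with matplotlib 3.10.9.

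The fits were tested on simulated data for this comparison, with the real genes' means and library sizes, a biological coefficient of variation of 0.16 and 200 changed genes. Over 15699 genes edgeR recovered 64 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 9 unchanged genes called. With an added GC trend that differed between replicates, over 15760 genes, it recovered 0 of 100 and 18 of 100. The GC correction brought this to 61 of 100 and 97 of 100, with 9 unchanged genes called. The added trend was the same in both groups. The simulation therefore does not test the correction where the group difference also goes with GC content, as in the real libraries (Spearman correlation −0.31). In a test of camera on 15714 simulated genes, a list of 30 genes shifted by 0.8 on the log2 scale had an unadjusted p of 3.9e-32. Of 100 random lists 3 had an unadjusted p under 0.05. The simulated genes were drawn independently, so this does not test camera on lists of correlated genes.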

Results

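RNA from HCT116 cells, an established human colon cancer line, was sequenced after knockdown of RBM25 by shRNA or after a control shRNA, with 2 libraries per group. RBM25 encodes an RNA-binding protein that works with the U1 snRNP in the choice of splice sites. The deposited counts per gene summed to 15528869 and 16982663 in the control libraries and to 15528274 and 16335555 in the RBM25 shRNA libraries. The labels do not say that the replicates came from separate cultures, so the edgeR p-values measure only the spread between these libraries, which may be technical. The camera p-values set a list's genes against all other genes, and do not measure how far a change would recur in new cultures. Values are means ± SD of TMM-scaled CPM (counts scaled to library size) with n = 2 per group, and log2 fold changes are RBM25 shRNA against control shRNA ± SE.

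The first question was whether the targeted transcript was lower in the knockdown libraries. RBM25 (ENSG00000119707, GRCh38 chromosome 14, 73058436 to 73123898, plus strand) stood at 155.3 and 114.9 CPM in the control libraries and at 44.0 and 35.7 CPM in the RBM25 shRNA libraries. Its mean fell from 135 ± 28.6 to 39.9 ± 5.90 CPM, which is 3.39-fold lower (log2 fold change −1.76 ± 0.30, edgeR adjusted p = 0.0195). The fold without 1 library ranged from −1.96 to −1.52, and the edgeR adjusted p rose to 0.119 without RBM25_sh replicate 1 and to 0.202 without RBM25_sh replicate 2.

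The series title concerns MNK2, the kinase encoded by MKNK2 that phosphorylates the cap-binding factor eIF4E. MKNK2 (ENSG00000099875, chromosome 19, 2037465 to 2051244, minus strand) had 244.6 and 425.3 CPM in the control libraries and 159.1 and 251.8 CPM in the RBM25 shRNA libraries. The ranges overlapped, and the difference of −0.71 ± 0.35 on the log2 scale was not past the threshold (edgeR adjusted p = 0.283). Without control_sh replicate 1 it was −1.04, while it was −0.25 without control_sh replicate 2 and −0.39 without RBM25_sh replicate 1. Replicate 2 had the higher value in both groups, so these fits compare unequal sets of replicates. Their swings do not by themselves show an unstable difference. After a correction for GC content, chosen after seeing the data, the MKNK2 difference was −0.48 ± 0.13 with an edgeR adjusted p of 0.0284. The values are totals over all transcripts of the gene, so the shares of the MKNK2 splice forms were not analysed here. None of the 25 measured genes of the list of MNK kinases, cap-binding factors and upstream p38 and ERK kinases was called, over all genes or adjusted over the list alone. Of these, 5 were called higher and 6 lower after the GC correction, among the lower MKNK2, RPS6KA5, a kinase downstream of p38 and ERK (−1.27 ± 0.15), and EIF4EBP1, a repressor of eIF4E (−0.97 ± 0.15). Among the higher were their paralogs EIF4EBP2 (0.61 ± 0.13) and RPS6KA4 (0.56 ± 0.12), the latter named after its values were seen.

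**Figure D1:**
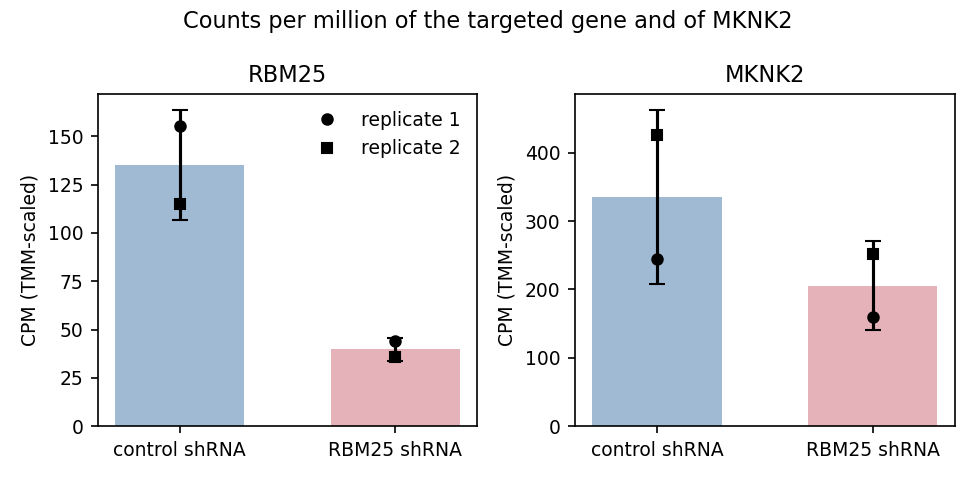
CPM (y axis, linear, TMM-scaled) of RBM25 and MKNK2 by group (x axis). Bars are means of 2 libraries, error bars are SDs, and points are the libraries. RBM25 lay at 35.7 to 44.0 CPM in the RBM25 shRNA libraries and at 114.9 to 155.3 CPM in the controls, while the MKNK2 values of the groups overlapped.

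More genes were called lower than higher in the RBM25 shRNA libraries. The largest increases among well expressed protein-coding genes included the cytosolic chaperone gene HSPA8, the cell-cycle kinase gene CDK6 and the WNT feedback gene AXIN2. The largest decreases included PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, the stress transcription factor gene DDIT3 and the arrestin-domain gene ARRDC4. Of 16091 genes tested, 491 passed the edgeR threshold, 105 higher and 386 lower, each by at least 2-fold; 388 of them were protein-coding.

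ATAD3C (chromosome 1, 1449689 to 1470158) rose from 0.759 ± 0.268 to 20.1 ± 3.12 CPM, a log2 fold change of 4.70 ± 0.41 (edgeR adjusted p = 0.0024). HSPA8 (chromosome 11, 123057489 to 123063230) rose from 458 ± 127 to 2696 ± 315 CPM, or 5.89-fold (2.56 ± 0.30, edgeR adjusted p = 0.00637). KRTAP2-3, a hair keratin-associated protein gene, rose by 3.25 ± 0.34. The other 7 of the 10 largest increases were FNDC10 at 2.26, the tetraspanin gene TSPAN1 at 2.20, ILDR2 at 2.18, the hemidesmosome collagen gene COL17A1 at 2.13, the chaperone gene HSPH1 at 1.92, AXIN2 at 1.92 and CDK6 at 1.89. ATAD3C, KRTAP2-3 and HSPA8 have closely related copies or processed pseudogenes, and their values are uncertain where reads could be split between them. Without RBM25_sh replicate 1, HSPH1 and CDK6 had edgeR adjusted p-values of 0.0632 and 0.056.

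LURAP1L (chromosome 9, 12775021 to 12822131) fell from 21.7 ± 2.11 to 1.40 ± 0.0038 CPM, 15.3-fold lower (log2 fold change −3.94 ± 0.35, edgeR adjusted p = 0.0024). PCK2 (chromosome 14, 24094053 to 24110598) fell from 170 ± 44.9 to 13.5 ± 5.52 CPM, 12.6-fold lower (−3.65 ± 0.38, edgeR adjusted p = 0.00488). GRAMD1B, a sterol transfer protein gene, fell 10.8-fold and ARRDC4 10.6-fold. The other 6 of the 10 largest decreases were BCAN at −3.21, RPE65 at −3.03, ZC3H6 at −2.96, the lens filament gene BFSP1 at −2.94, the amino acid transporter gene SLC43A1 at −2.93 and DDIT3 at −2.93. LURAP1L and BCAN overlap antisense genes that were also called lower, PCK2 and DDIT3 overlap protein-coding genes on the opposite strand, and without stated stranded counting the sources of such reads cannot be separated.

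A fit without 1 library takes its spread between libraries only from the group that keeps 2. The control libraries lay further apart than the RBM25_sh libraries (chi-square per degree of freedom of 71.2 and 26.8). Calls lost without an RBM25_sh library therefore do not by themselves show that the gene's change was unstable. The count of changed genes depended on the libraries. It was 204 without RBM25_sh replicate 1, 321 without RBM25_sh replicate 2, 1033 without control_sh replicate 2 and 2389 without control_sh replicate 1. Within each group, replicate 2 exceeded replicate 1 in GC-rich genes and lay below it in AT-rich genes, with a Spearman correlation with GC content of 0.82 in the control and 0.84 in the RBM25 shRNA libraries across 10378 genes, which are not independent replicates. The log2 fold change between groups had a Spearman correlation of −0.31 with GC content over the same genes. A fit without 1 library compares unequal sets of replicates. Its fold changes and list medians can therefore also shift with the GC difference between replicates. With each library's GC trend removed, a correction chosen after seeing the data, 4534 of 16091 genes passed the edgeR threshold, 2033 higher and 2501 lower. Of the genes called, 44.8% were then higher against 21.4% before, and the 491 genes were all among them, in the same direction. Counts of members called after this correction, in any list, are no result about the list where they are near these shares of all 16091 genes.

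**Figure D2:**
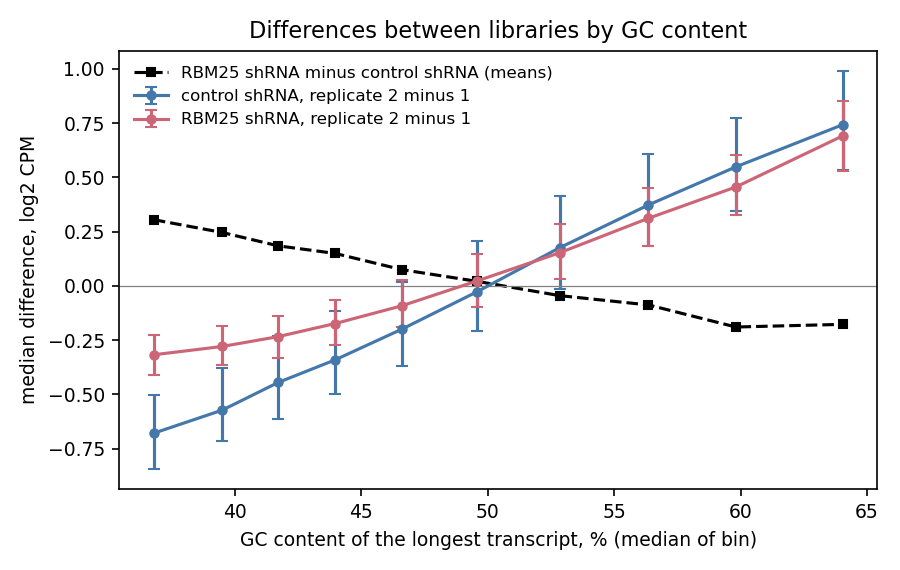
Median difference in log2 CPM (y axis) by the GC content of each gene's longest transcript in percent (x axis), in 10 bins of 1037 or 1038 genes. Coloured points are replicate 2 minus replicate 1 in each group with bars for the quartiles, and black squares are the group difference. In the control libraries the median went from −0.68 in the lowest bin to 0.74 in the highest, and in the RBM25 shRNA libraries from −0.32 to 0.69.

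As lists, heat shock chaperone genes were higher after RBM25 knockdown, and genes of ATF4 and the unfolded protein response were lower. Of 16 measured heat shock genes 5 rose and none fell, and 13 rose when adjusted over the list alone. The 5 were HSPA8, HSPH1, the co-chaperone gene DNAJA1 (1.88 ± 0.30), the mitochondrial chaperonin gene HSPE1 (1.61 ± 0.29) and HSPA1B (from 19.7 ± 7.40 to 55.7 ± 8.97 CPM), the last named after its values were seen. The list's median was 1.21 (camera adjusted p = 1.3e-08, or 0.330 with an estimated correlation). Here and below, the test with an estimated correlation has only 2 residual degrees of freedom. HSPE1 overlaps HSPD1 on the opposite strand, and HSPA1B has a near-identical neighbour, HSPA1A, so both values are uncertain.

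Of 34 measured ATF4 and unfolded protein response genes 9 fell and none rose, and 20 fell when adjusted over the list alone. DDIT3, which encodes CHOP, fell from 66.2 ± 24.8 to 8.70 ± 1.40 CPM, and the pseudokinase gene TRIB3 fell 5.18-fold (−2.37 ± 0.33). ERN1, the endoplasmic reticulum stress sensor IRE1, changed by −1.59 ± 0.27, and PHGDH, the first enzyme of serine synthesis, by −1.67 ± 0.31. The list did not fall throughout. Even after the GC correction ATF4 itself (−0.20 ± 0.15), CALR (0.29 ± 0.14) and PDIA4 (0.09 ± 0.16) were not called, while HSPA5 (−0.75 ± 0.16) was called lower. These genes were named after their values were seen. The list's median was −0.87 (camera adjusted p = 1.8e-07; adjusted p = 0.354 with an estimated correlation). Both lists also passed the camera threshold without any 1 library. Among the genes named here from these lists, HSPH1, DNAJA1 and TRIB3 lost their edgeR call without RBM25_sh replicate 1, and HSPE1, HSPA1B, ERN1 and PHGDH without either RBM25_sh replicate.

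Growth-related lists were higher as groups, with few single genes past the edgeR threshold before the GC correction. Ribosome biogenesis and MYC target genes had a median of 0.43, with 1 of 36 called, the chaperonin gene HSPE1 that is also in the heat shock list, and 4 adjusted over the list alone (camera adjusted p = 9.3e-05; adjusted p = 0.330 with an estimated correlation). G1/S and DNA replication genes had a median of 0.35, with 1 of 40 called, the replicative helicase gene MCM4 (1.26 ± 0.27), and 2 adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.479 with an estimated correlation). G2/M and mitosis genes had a median of 0.28 with none of 40 called over all genes or adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.731 with an estimated correlation). HMMR, a spindle protein gene, went against the G2/M list at −1.18 ± 0.33 without passing (edgeR adjusted p = 0.0884), and after the GC correction it was −1.40 ± 0.13 (edgeR adjusted p = 2.5e-04). That correction called 20 of the 36 ribosome biogenesis genes and 14 of the 40 G1/S genes higher with none lower, and 8 of the 40 G2/M genes higher and 3 lower. MYC itself, named after its values were seen, was called lower after the correction (−0.59 ± 0.13). Without control_sh replicate 2 the camera adjusted p was 0.0669 for G1/S and 0.591 for G2/M, and for G2/M it was 0.224 without RBM25_sh replicate 1 and 0.0656 after the GC correction. The G1/S median was 0.23 without control_sh replicate 2, and the G2/M median ranged from 0.14 to 0.62 without 1 library. The edgeR adjusted p of MCM4 was 0.326 and 0.282 without RBM25_sh replicates 1 and 2.

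Targets of WNT signalling and genes of cholesterol and lipid synthesis were also higher. Of 19 WNT targets 3 rose and none fell, AXIN2, the ligand gene BMP4 (1.59 ± 0.27) and the cyclin D1 gene CCND1 (1.45 ± 0.27), and 4 rose when adjusted over the list alone (median 0.26, camera adjusted p = 0.0453; adjusted p = 0.647 with an estimated correlation). Of 32 cholesterol and lipid synthesis genes 4 rose and none fell, among them INSIG1 (1.48 ± 0.28), IDI1 (1.52 ± 0.32) and FDFT1 (1.18 ± 0.26), and 7 rose when adjusted over the list alone (median 0.40, camera adjusted p = 0.0011; adjusted p = 0.330 with an estimated correlation). With the GC correction 6 WNT targets were called higher and 2 lower, MYC (−0.59 ± 0.13) and DKK1 (−0.66 ± 0.13), both named after their values were seen, and 17 of the cholesterol and lipid genes were called higher and 1 lower. The WNT list's camera adjusted p was 0.0843 without control_sh replicate 1, 0.0719 without control_sh replicate 2 and 0.157 without RBM25_sh replicate 2. BMP4, CCND1, INSIG1, IDI1 and FDFT1 lost their edgeR call without either RBM25_sh replicate. CCND1 overlaps LTO1 on the opposite strand, so part of its reads cannot be assigned.

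Core spliceosome genes and SR proteins with their kinases were slightly higher as groups, and no member of these 2 lists was called alone before the GC correction. Core spliceosome genes had a median of 0.31, with 32 of 40 above 0 and none called over all genes or adjusted over the list alone (camera adjusted p = 0.00221; adjusted p = 0.330 with an estimated correlation). SNRPB2, a U2 snRNP protein gene, was the nearest at 0.91 ± 0.28 (edgeR adjusted p = 0.105). The GC correction left 15 of the 40 called higher and none lower, SNRPB2 among them (0.65 ± 0.16, edgeR adjusted p = 0.0162). SR proteins and their kinases had a median of 0.33, with 20 of 24 above 0 and none called over all genes or adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.647 with an estimated correlation). SON, an SR-type splicing cofactor gene, had the smallest p of that list at 0.73 ± 0.28 (edgeR adjusted p = 0.178). After the GC correction SON (0.71 ± 0.18, edgeR adjusted p = 0.0173) was 1 of 3 SR genes called higher, with none lower. These 3 of 24 were near the share of all genes called higher after that correction. The SR list's camera adjusted p was 0.220 without control_sh replicate 2, 0.223 without RBM25_sh replicate 1 and 0.0729 after the GC correction, and its median was 0.22 without control_sh replicate 2.

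Interferon-stimulated genes and replication-dependent histone genes were lower. Of 30 interferon-stimulated genes 1 fell, the HLA class I gene HLA-B (−1.40 ± 0.27), and 12 fell when adjusted over the list alone (median −0.78, camera adjusted p = 1.4e-04; adjusted p = 0.354 with an estimated correlation). HLA-B is highly polymorphic, has close paralogs and overlaps HLA-C in the annotation, so its value is uncertain, and it lost its edgeR call without either RBM25_sh replicate. Of the 30, 16 were called lower and none higher after the GC correction. The 12 measured histone genes all had negative log2 fold changes (median −0.53, camera adjusted p = 0.0451; adjusted p = 0.620 with an estimated correlation), with none called over all genes and 1 adjusted over the list alone. That gene, HIST2H2AC, had few counts, 26 and 17 in the control libraries and 2 and 1 in the RBM25_sh libraries. The histone list's camera adjusted p was 0.243 without control_sh replicate 1, 0.224 without RBM25_sh replicate 1, 0.0567 without RBM25_sh replicate 2 and 0.114 after the GC correction, and its median was −0.25 without RBM25_sh replicate 1. Cytosolic ribosomal protein genes had a median of 0.08, which was −0.04 when scaled by library totals −0.18 without control_sh replicate 1, where the list's direction turned, and 0.45 without control_sh replicate 2. None of the 55 ribosomal protein genes was called over all genes or adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.777 with an estimated correlation), and the camera adjusted p was 0.0835 and 0.126 without RBM25_sh replicates 1 and 2.

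**Figure D3:**
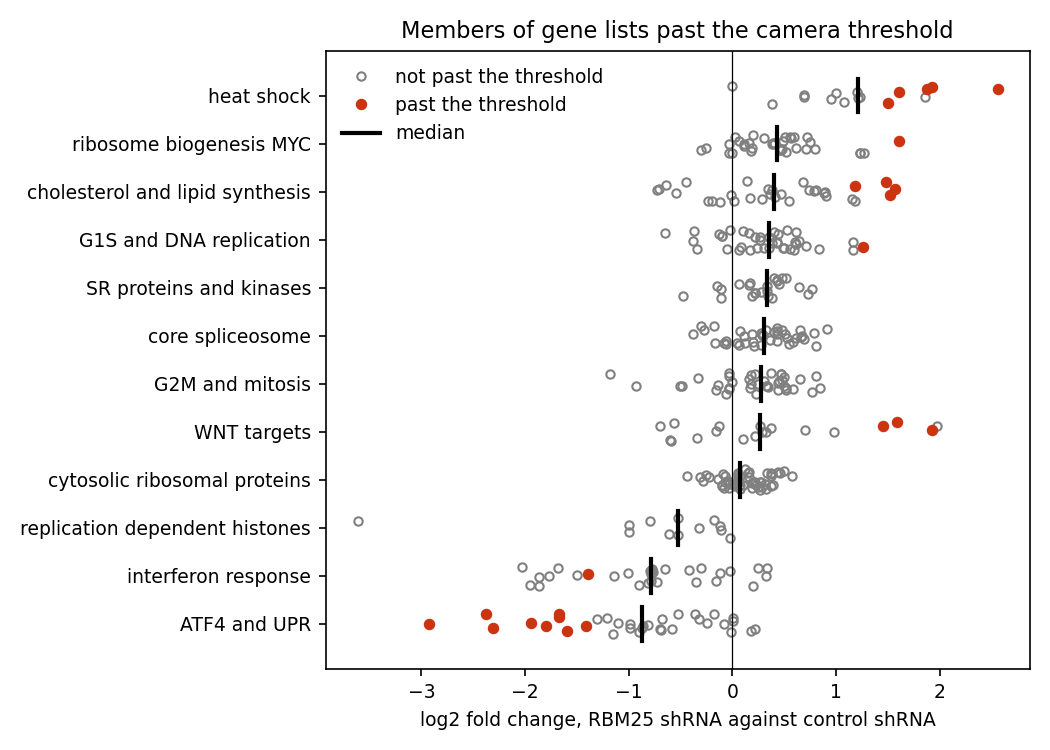
Log2 fold change (x axis, RBM25 shRNA against control shRNA) of each measured member of 12 of the 13 gene lists past the camera threshold (y axis). Filled points are members past the edgeR threshold, open points the rest, and bars are list medians, which ran from −0.87 for ATF4 and unfolded protein response genes to 1.21 for heat shock genes.

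The other 13 tested lists did not pass. Their camera adjusted p-values were 0.0582 for nonsense-mediated decay factors, 0.0815 for immediate-early and ERK feedback genes, 0.212 for hypoxia and glycolysis, 0.241 for absorptive colonocyte markers, 0.290 for markers of non-epithelial cells, and 0.331 for both U1 snRNP partners and mitochondrial mRNAs. They were 0.594 for the BCL2 family and for oxidative phosphorylation, 0.601 for epithelial-mesenchymal transition, 0.637 for hnRNPs, 0.726 for inflammatory NF-kappaB genes and 0.791 for the MNK and eIF4E list. The test direction of the MNK and oxidative phosphorylation lists was up while their medians and means were below 0, and the BCL2 and hnRNP lists had a mean below 0 with a median and test direction above 0.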

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

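Corrections for GC content and length were chosen after seeing the data. The number of changed genes, 491, was 466 with DESeq2 size factors, 534 with library totals, 590 with a stricter filter, 374 with limma-voom and 491 at a minimum of 2-fold. It was 1438 without a filter, where 30897 genes were tested, 1085 with the DESeq2 Wald test, 215 with limma-trend on log2(FPKM + 1), 4534 after the GC correction and 4760 after the GC and length correction. On log2(FPKM + 0.1) without a filter limma-trend called 0 genes, with 3791 at an unadjusted p under 0.05. Leaving out 1 library gave 204 to 2389 genes. The libraries share only replicate numbers; same-numbered libraries of both groups deviated from their group means with a correlation of 0.47 across genes. A replicate block gave 5722 genes, and a replicate block with the GC correction gave 6026. The RBM25 log2 fold change stayed negative in all 15 alternatives and missed the threshold on log2(FPKM + 1) (−1.46, adjusted p = 0.0572) and in 2 of the fits without 1 library (range −1.96 to −1.52). MKNK2 stayed negative in all 15 and passed the threshold with the replicate block (−0.69), with the GC correction (−0.48), with GC and length (−0.47), with the replicate block with GC correction (−0.47) and in 1 of the fits without 1 library (range −1.04 to −0.25). Of 13 gene lists, an estimated inter-gene correlation left 0 (2 at an unadjusted p under 0.05). With its 2 residual degrees of freedom few lists could pass, so this does not settle whether gene correlation made the calls. The fry test called 1, nonsense-mediated decay factors, which is not among the 13. The count was 13 with library totals, 10 after the GC correction and 13 with the replicate block, of which 12 were shared with the 13 above; the block ended the WNT list's call (adjusted p = 0.101) and called immediate-early and ERK feedback genes lower (adjusted p = 0.0490), which were at 0.0829 with the block and the GC correction. It was 9 with both, and 9 or 10 without 1 library. In lists, the camera direction turned in 1 result, cytosolic ribosomal proteins without control_sh replicate 1 (range of medians without 1 library −0.18 to 0.45). With library totals that list's median was also negative, though its camera direction did not turn. For 47 other genes compared no alternative turned a direction, 18 results newly passed and 63 no longer passed, of which 24 were without RBM25_sh replicate 1, 17 without RBM25_sh replicate 2 and 17 on log2(FPKM + 1). Scaling by library totals moved the median of all genes by −0.11. Fits without 1 library take their spread only from the group that keeps 2, and the control pair was the more spread. Beyond this and the other genes tested, the cause of these differences was not tested. The transcript usage and MKNK2 transcript share results and their alternatives were not run. With 2 libraries per group and 15528274 to 16982663 counts each, no changed gene had a log2 fold change below 1.14 in size.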

Other observations

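Outside the lists that passed, single genes of several groups changed after RBM25 knockdown. The glucose transporter gene SLC2A1 rose from 418 ± 20.8 to 1032 ± 101 CPM, while the lipoprotein lipase inhibitor gene ANGPTL4, in the same hypoxia and glycolysis list, fell from 37.1 ± 9.6 to 8.61 ± 0.89 CPM, and 33 other members did not pass. With the GC correction 2 of the 35 members were called higher and 11 lower, among them VEGFA (−0.99 ± 0.13) and HK2 (−0.92 ± 0.13). Among U1 snRNP proteins and partners, FUBP1 rose by 1.21 ± 0.27 (edgeR adjusted p = 0.0481), RBM25 itself was the 1 that fell, and 13 did not pass. The anti-apoptotic gene BCL2L2 changed by −1.55 ± 0.29 (edgeR adjusted p = 0.0283) and was the 1 called of 29 BCL2 family and caspase genes. FUBP1, SLC2A1 and BCL2L2 lost their edgeR call without either RBM25_sh replicate and ANGPTL4 without RBM25_sh replicate 1. All were called again after the GC correction, which called 5 higher and 3 lower of the 15 U1 snRNP genes and 6 higher and 3 lower of the 29 BCL2 family and caspase genes.

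Of 27 markers of immune, endothelial, fibroblast, muscle and neuronal cells 6 were measured, and 1 was called, KDR, with 12 and 20 counts in the control libraries and 0 in both RBM25_sh libraries, at least 4.78-fold lower against a floor of 3 counts per library, and it lost its edgeR call without either RBM25_sh replicate. Adjusted over the list alone, and also after the GC correction, 2 of the 6 were lower and 1 was higher. After the correction these were KDR, ACTA2 (−2.08 ± 0.41) and, higher, MYH11 (1.41 ± 0.26), and both muscle markers overlap genes on the opposite strand. The only measured goblet or enteroendocrine marker, FCGBP, fell from 9.03 ± 1.18 to 1.32 ± 1.11 CPM, with 8 and 33 counts in the RBM25_sh libraries. Its log2 fold change of −2.76 was −2.08 without RBM25_sh replicate 1 and −4.02 without RBM25_sh replicate 2, and it was not past the threshold on log2(FPKM + 1). Of 8 absorptive colonocyte markers, TSPAN1 alone was called, and 2 were higher after the GC correction. A single library held most counts of RN7SL2, a signal recognition particle RNA gene noticed after its values were seen, with 16539 counts in control_sh replicate 2 against 80, 56 and 231 in the others.

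Of the tests below, those of the larger part of the GC trend, of the SR, G2/M and histone lists, and of MT-RNR1 against mitochondrial RNA and poly(A) tails were chosen only after the result was seen.

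Same-numbered libraries of both groups deviated together, with a correlation of 0.47 across genes. Removing each library's trend on gene length left it at 0.454, which argues against length. Removing the GC trend brought it to 0.138, between the bounds of 0.1 and 0.3 set beforehand for GC content being or not being the whole cause, so that remains open. The GC correction took away 82.1% of the covariance, which is consistent with GC content as the larger part, and lowered the common biological coefficient of variation from 0.252 to 0.144. Whether a shared preparation, sequencing run or day may lie behind the GC trend was not tested, since the labels give no batch.

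Heat shock genes higher and ATF4 targets lower were set against GC content and against 1 library. After the GC correction the medians were 1.09 and −0.83, with 15 of 16 heat shock genes called higher. Of the 34 ATF4 and unfolded protein response genes 22 were called lower. Without any 1 library the medians came no nearer to 0 than 0.808 and −0.737. Neither GC content nor 1 library therefore accounts for these lists as the whole cause. Of the other 11 lists past the threshold, 8 stayed past it after the GC correction. The SR list's median went from 0.33 ± 0.06 to 0.139 ± 0.069 (bootstrap SE) and the G2/M list's from 0.28 ± 0.08 to 0.178 ± 0.062, both within 1 SE of the values of 0.166 and 0.139 that divide a larger from a smaller part due to GC content, which leaves that open, and the histone list's from −0.53 ± 0.18 to −0.593 ± 0.217, which argues against GC content as its larger part. With the correction that ended these 3 calls, the spread of all genes' z-scores rose from 1.51 to 1.84. The gap between a list's mean z-score and that of other genes changed by less. It went from 0.699 to 0.756 for G2/M, from −1.06 to −1.03 for the histones and from 0.972 to 0.869 for the SR list. The G2/M call therefore ended with a wider spread and not with a smaller gap. Whether the wider spread ended the SR and histone calls was not tested. A response to RBM25 loss or to the shRNA may lie behind the heat shock and ATF4 changes, a hypothesis that 1 shRNA target and 2 libraries per group leave untested.

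MT-RNR1, the mitochondrial 12S rRNA gene, named after its values were seen, rose 8.61-fold (3.11 ± 0.26, edgeR adjusted p = 0.0024), its neighbour MT-TV 7.02-fold and another tRNA gene, MT-TE, 3.19-fold, and the 16S rRNA gene MT-RNR2 had a log2 fold change of 0.89 ± 0.24 (edgeR adjusted p = 0.0775). The 13 mitochondrial mRNAs had a median of 0.0807, which argues against a like rise of all mitochondrial RNA, although MT-ND2 (0.96 ± 0.30) and MT-ND1 (0.68 ± 0.28), not past the edgeR threshold, were called higher after the GC correction. MT-RNR1 exceeded MT-RNR2 by 2.22 on the log2 scale. The 12 of 22 listed histone genes that were measured had a median of −0.53, or −0.25 without RBM25_sh replicate 1. These values argue against a like rise of all RNA without a poly(A) tail. A rise of part of such RNA remains open, since histone transcripts lack a tail only for the most part. By position, every tested mitochondrial gene from MT-RNR1 to MT-ND2 (648 to 5511) was higher in both RBM25_sh libraries than in either control. This was noticed after the values were seen. The stretch includes MT-TI (1.62 ± 0.44), but only MT-RNR1 and MT-TV in it passed the edgeR threshold. Some of its tRNA genes had few counts, such as MT-TQ with 4 and 8 in the controls. Beyond it genes went both ways, such as MT-TG (0.99 ± 0.33) and MT-TC (−0.75 ± 0.29), neither past the edgeR threshold. After the GC correction MT-RNR1 stood at 3.04, which argues against GC content. Reads from nuclear copies of the mitochondrial genome and a change in processing or decay of the 12S rRNA may each account for it and were not tested.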
